A study of Mus musculus with 6 samples.

How the data were processed

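RNA from heart samples of 6 mice was measured on Affymetrix expression arrays, with 1 array per mouse. Per the labels, 3 mice carried a knockout of Tmbim1 and 3 were Flox wild type animals on a C57BL/6 background. All 6 were 8 weeks old and had undergone aortic banding (written as binding in the labels) for 2 weeks, and biotin-labelled cRNA was made from 400 ng of total RNA. The labels describe the mice as separate biological samples.

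The deposited values are log2 signals per probe set. RMA and limma are the tools named per the submitters' processing notes, with versions and settings not given in the sources used here. RMA subtracts background, makes the distributions of the arrays alike by quantile normalization and summarises the probes of a probe set on the log2 scale. It therefore removes any overall shift in signal between the groups, and differences near the dim and the bright end of the scale can be compressed. No centring per gene was seen in the values, whose array medians lay between 4.24 and 4.28. The array scans, their dates and probe-level detection calls were not analysed here, so no scan batch was tested.

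The table had 38208 rows. The 13 control probe sets were left out of the tests, which left 38195 probe sets. The platform annotation supplied with the data gave 34325 of them 1 gene symbol, 62 several and 3808 none, and 0 symbols changed when they were looked up by Entrez identifier in the GRCm38.p6 gene table. Probe sets with several symbols or none were tested but not named. For statements about genes, each of the 18029 genes was represented by its main probe set, the one with the highest mean log2 value over all 6 arrays. Gene coordinates were not used, except to order genes along a chromosome.

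Knockout was compared with wild type by limma (version 3.58.1, in R 4.3.3), with lmFit and eBayes on the deposited log2 values, two-sided, and Benjamini-Hochberg adjustment over the 38195 probe sets at an adjusted p threshold of 0.05. Unless stated otherwise, every adjusted p of a gene below comes from this limma fit, and every difference is knockout minus wild type on the log2 scale with n = 3 mice in each group. Gene lists were tested by camera from limma, with its preset inter-gene correlation of 0.01, on the main probe sets. The 29 biology and cell type lists were adjusted as 1 family and the 4 technical lists (heat shock genes, clock genes, sex-linked genes and chromosome 1 neighbours of Tmbim1) as another. Members of a list were counted by their main probe set, with adjustment over all probe sets, and were also counted when adjusted over the list alone. The lists, the tests, the rule for naming genes and the alternatives were fixed before the data were examined, unless a sentence says otherwise.

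The rule named Tmbim1, the 12 largest rises and 12 largest falls among main probe sets that passed the threshold with all 3 knockout arrays on 1 side of all 3 wild type arrays, up to 4 members of each list with the smallest unadjusted p, and a set of genes often followed in cardiac hypertrophy (Nppa, Nppb, Myh7, Myh6, Col1a1, Col3a1, Ccn2, Tlr4, Tnf, Il6 and Il1b) whatever their p. Myh6 was not analysed here.

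The code was tested on simulated data with the real probe sets' means, in which 200 of 38195 probe sets were changed. It recovered 9 of 68 probe sets changed by 0.5 on the log2 scale, 60 of 66 changed by 1 and 66 of 66 changed by 2. Of 141 calls, 6 were false. Of 30 simulated lists of 20 genes, the 3 shifted by 0.5 were called, with 0 of the 27 others. The simulated genes varied independently, which genes in hearts do not. Their SDs were drawn from the variance distribution that eBayes assumes, fitted to the real values, so recovery and false calls may be worse in real data.

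The alternatives were a replicate block, a trended and a robust variance prior, array quality weights, a second quantile normalization, median centring, a filter that keeps probe sets above the 40th percentile of mean signal, 1 probe set per gene, an ordinary two-sample test, an unadjusted p under 0.05 with a fold change of 1.5, and each array left out in turn. For lists they also included an estimated inter-gene correlation, the rotation test fry and the mean of all probe sets of a gene. A fit without knockout replicate 1 and wild type replicate 3 was added after seeing the data. The ordinary test and the unadjusted rule were run only for counts of probe sets. They are not among the alternatives counted for a gene or a list. The number of arrays, 3 in each group, limits the precision of every value.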

Results

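Gene expression was measured in the hearts of 3 Tmbim1 knockout mice and 3 Flox wild type mice, all collected 2 weeks after aortic banding, a surgical constriction that raises the pressure against which the left ventricle pumps. TMBIM1 is a membrane protein of endosomes and lysosomes. The comparison asks how the pressure-loaded heart differs between Tmbim1 knockout and Flox wild type mice. How the deletion was made, and whether the groups were littermates, is not settled by the information used here. Other genetic differences between the groups are therefore not separated from the loss of Tmbim1. Hearts without surgery were not analysed here, so the values describe a difference between genotypes in banded hearts and not the response to banding. The arrays correlated with one another at 0.989 to 0.996 across probe sets. On the first principal component, which held 37.4% of the variance, the 3 knockout arrays lay between 11.0 and 23.4 and the wild type arrays at -8.48, -9.65 and -37.0, the last being wild type replicate 3.

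Tmbim1 itself was lower in every knockout heart. Its signal averaged 8.43 ± 0.13 (SD, n = 3) in wild type hearts and 7.53 ± 0.04 (SD, n = 3) in knockout hearts, a difference of -0.91 (SE 0.10, limma adjusted p = 0.00579) or 1.87-fold lower expression. The gene has 1 probe set on the array, and where its probes lie relative to the deleted part of the gene is not known. It is also not known here whether all cells of the heart carry the deletion. Whether the remaining signal comes from intact transcript, or from cells that kept the gene, therefore cannot be told. Without knockout replicate 2 the adjusted p rose to 0.0512. Of the 7 TMBIM family genes measured, 1 passed by limma, Tmbim1 itself, which was also the 1 with an unadjusted p under 0.05, with Tmbim6 at -0.20, Ghitm at -0.12 and Grina at -0.13.

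Knockout hearts had higher expression of several cytokine, immediate early, heat shock and fetal cardiac genes, and lower expression of genes such as Asb15, Lpin1 and Kcnip2. Among main probe sets past the threshold, the largest rises were those of Il6 and Wdfy1. Il6, the cytokine interleukin 6, rose by 2.68 (SE 0.28, adjusted p = 0.00485). Its wild type mean of 2.35 lay below the lower quartile of every array (2.72 to 2.78), so the size of its rise is uncertain. Wdfy1, an endosomal adaptor in Toll-like receptor signalling that lies 56 measured genes from Tmbim1 on chromosome 1, rose by 2.65 (SE 0.11, adjusted p = 1.30e-05). Next were the inducible heat shock genes Hspa1b (2.33) and Hspa1a (2.20), the transcription factor Egr2 (2.19) and the stress-induced cardiac gene Sprr1a (2.16). The acute phase protein gene Serpina3n (1.80), Ptgs2 (1.76), Timp1 (1.72), Apold1 (1.67), Atf3 (1.66) and Rab4a (1.65) came after these. The largest falls were those of the integrin gene Itgb6 (-1.16), the muscle ubiquitin ligase adaptor Asb15 (-1.08), the secreted protease Htra1 (-1.05), the muscle protein gene Ky (-1.04) and the transcription factor Prox1 (-0.91). Gm19277 (-0.91), Zfp827 (-0.86), Cadm4 (-0.84), Ttc30a1 (-0.82), Cndp2 (-0.79) and Lpin1 (-0.78), which encodes a phosphatidate phosphatase of lipid synthesis, followed. Other, dimmer probe sets of Itgb6 (-0.07), Ky (0.06), Prox1 (-0.17 and -0.36), Asb15 (-0.33), Zfp827 (-0.46), Kcnip2 (0.11 and -0.71) and Fhl1 (0.19) did not pass.

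In all, 161 of 38195 probe sets passed the threshold, 91 higher and 70 lower in knockout hearts, and besides 6 that were not assigned to a single gene these belonged to 73 genes that rose and 62 that fell. Over all probe sets tested, the 3 knockout arrays lay wholly above or below the 3 wild type arrays in 15.2%, where chance gives 10%. An unadjusted limma p under 0.05 was seen in 4034 of the 38195, where chance gives 1910. Counts of list members at that unadjusted threshold are to be read against this share. The count of 161 fell to 38 without knockout replicate 2, 55 without knockout replicate 1, 72 without knockout replicate 3, 69 without wild type replicate 2, 69 without wild type replicate 3 and 86 without wild type replicate 1. Of the 37 named genes past the threshold, 15 stayed past it with any single array left out, namely Il6, Wdfy1, Hspa1b, Serpina3n, Ptgs2, Apold1, Atf3, Rab4a, Nppb, Tnf, Il1b, Ccl3, Ccl4, Ier3 and Gm19277. Sprr1a (adjusted p = 0.0490) lost its call in 11 of 15 alternatives, 5 of which kept all 6 arrays, Ttc30a1 in 9 of 15, Hspa1a, Col3a1, Kcnip2 and Pfkm in 8 of 15, and Itgb6 in 7 of 14.

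**Figure D1:**
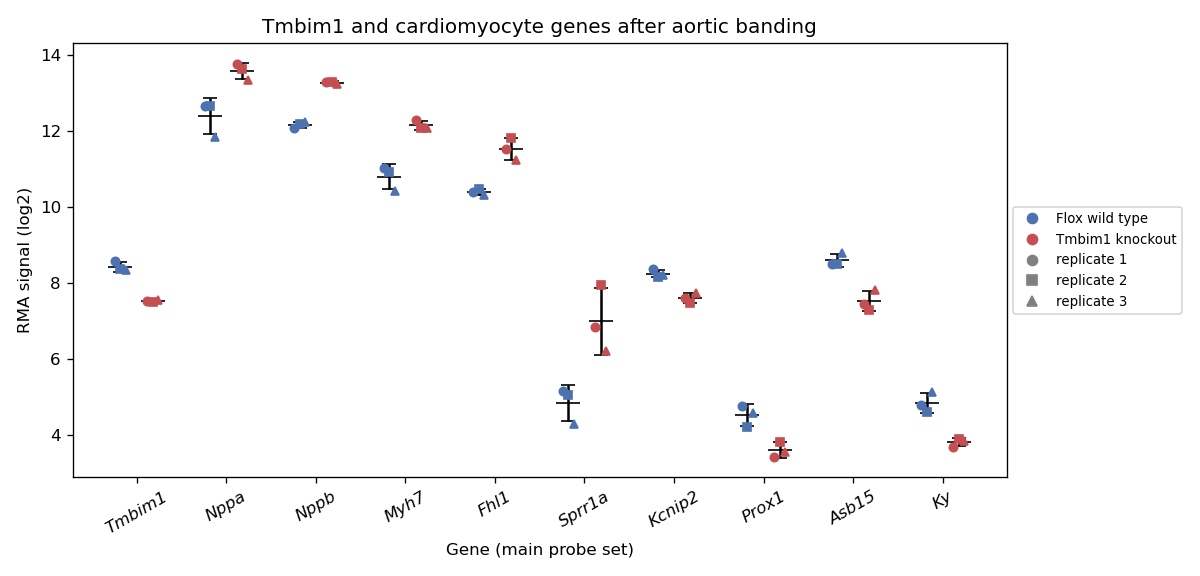
Signal (log2) of Tmbim1 and 9 cardiac or muscle genes in each array, with 1 symbol per mouse and the mean and SD of 3 mice as a bar. Tmbim1, Kcnip2, Prox1, Asb15 and Ky were lower in all 3 knockout hearts, and Nppa, Nppb, Myh7, Fhl1 and Sprr1a were higher in all 3. All of these genes had passed the threshold, and all 161 probe sets past it had the groups apart.

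Fetal and hypertrophy genes, which adult ventricles re-express under load, stood higher in knockout hearts. Of 14 measured members, 4 rose over all probe sets and 6 when adjusted over the list alone. Nppb, the B-type natriuretic peptide gene, rose by 1.11 (SE 0.09, adjusted p = 0.00124), from 12.17 ± 0.08 (SD, n = 3) to 13.28 ± 0.04 (SD, n = 3). Myh7, the slow myosin heavy chain gene, rose by 1.36 (SE 0.16, adjusted p = 0.00638), Fhl1, a LIM-domain protein of the sarcomere, by 1.13 (SE 0.14, adjusted p = 0.0110), and Nppa, the atrial natriuretic peptide gene, by 1.19 (SE 0.21, adjusted p = 0.0496). Nppa stood at the top of the scale, its 13.78 in knockout replicate 1 being that array's maximum, so its difference can be understated. Ccn2, a connective tissue growth factor, was at 0.61 and did not pass (adjusted p = 0.0797). The list had a median difference of 0.55 (camera adjusted p = 1.98e-10; adjusted p = 0.306 with an estimated correlation). Without knockout replicate 1, Nppb and Myh7 remained past the threshold, Fhl1 and Nppa did not (adjusted p = 0.0569 and 0.202), and the list median was 0.43. Without both that array and wild type replicate 3 the list median was 0.19 (adjusted p = 3.39e-07). Nppa lost its call in 9 of 15 alternatives, and with single arrays left out it kept it only without wild type replicate 3 (0.92, adjusted p = 0.0437). Myh7 lost its call without knockout replicate 2 (adjusted p = 0.0505).

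Knockout replicate 1 also carried atrial genes at levels seen on no other array. The atrial myosin light chain genes Myl7 and Myl4 and the calcium pump regulator Sln stood at 12.86, 12.98 and 12.17 there, 9.17, 8.36 and 9.58 above the mean of the other 5 arrays. The list of atrial markers had a median difference of 1.28 (camera adjusted p = 0.000235; adjusted p = 0.436 with an estimated correlation), and 1 of its 10 members, Nppa, passed. Without that array the median was 0.02 and the list no longer passed (adjusted p = 0.273). Nppa and Myl4 belong to both the atrial and the fetal list.

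**Figure D2:**
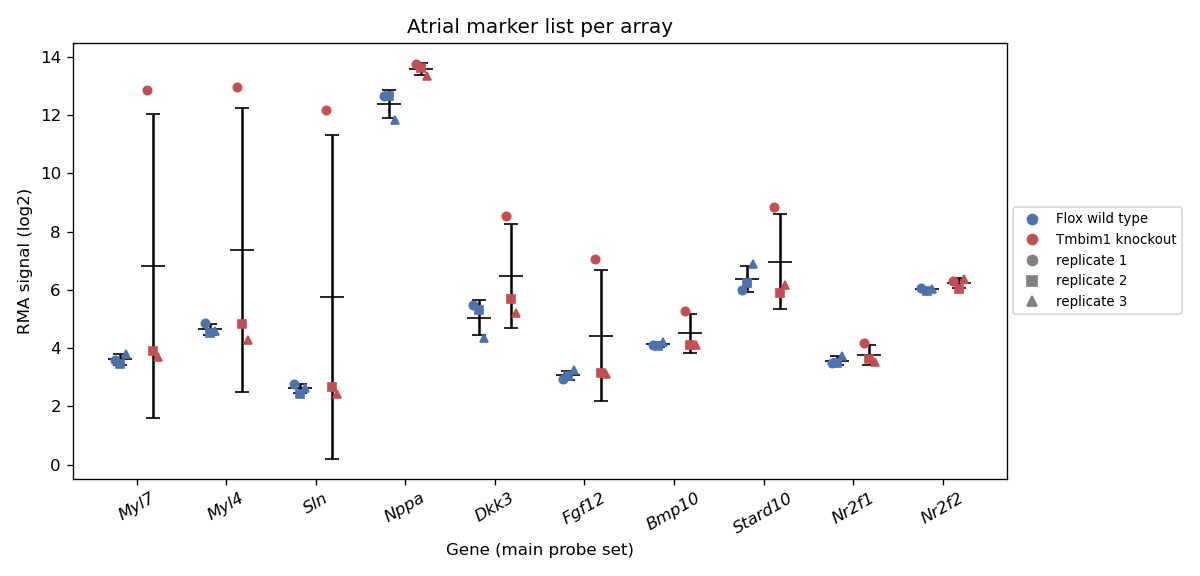
Signal (log2) of the 10 atrial marker genes in each array, with 1 symbol per mouse and the mean and SD of 3 mice as a bar. In knockout replicate 1, Myl7, Myl4 and Sln lay above 12, and in the other 5 arrays they lay below 5.

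Genes of adult cardiomyocyte contraction and calcium handling leaned lower in knockout hearts. All 21 measured members had a negative difference, with a median of -0.15, and 1 fell past the threshold over all probe sets against 4 when adjusted over the list alone. That one was Kcnip2, a subunit of the channel for the transient outward potassium current, at -0.64 (SE 0.11, adjusted p = 0.0408). The ryanodine receptor gene Ryr2 (-0.41) and the potassium channel genes Kcnd2 (-0.41) and Kcnq1 (-0.39) did not pass. The list passed by camera (adjusted p = 3.06e-06) and lost its call with adjusted p = 0.328 with an estimated correlation. Without wild type replicate 3, the array farthest out on the first principal component, the median was -0.13 (adjusted p = 0.000118). In the same hearts the medians of other cell types were 0.26 for macrophage and monocyte markers, 0.25 for fibroblast markers, 0.08 for endothelial markers and -0.10 for T and NK cell markers, and that of matrix genes was 0.58. Lower expression within cardiomyocytes was not separated from a change in the mix of cells.

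Fatty acid oxidation genes were lower as a list, with a median of -0.34 (camera adjusted p = 8.21e-09; adjusted p = 0.411 with an estimated correlation). Of 22 members, 0 passed by limma at their main probe set and 15 had an unadjusted p under 0.05, while 13 fell and 1 rose when adjusted over the list alone. Other, dimmer probe sets of Ppargc1a (-0.98 and -0.82) and Hadhb (-0.72) did pass. Cpt2, which acts in the mitochondrial import of fatty acids, was at -0.60, the trifunctional protein gene Hadha at -0.54 and Ucp3 at -0.52, while Angptl4, an inhibitor of lipoprotein lipase, was at 0.62. All 25 oxidative phosphorylation genes had a negative difference with a median of -0.13 (camera adjusted p = 2.72e-05; adjusted p = 0.539 with an estimated correlation), and 0 passed by limma over all probe sets or within the list, with 5 at an unadjusted p under 0.05. Sdha was at -0.35 and Cox7a1 at -0.30. Glycolysis and glucose uptake genes did not pass as a list (median 0.01, adjusted p = 0.726). Within it the muscle phosphofructokinase gene Pfkm fell by 0.59 (SE 0.10, adjusted p = 0.0415), and when adjusted over the list alone 4 fell and 2 rose, with the muscle glucose transporter Slc2a4 at -0.54 and the ubiquitous one, Slc2a1, at 0.69. Without wild type replicate 3 the fatty acid list median was -0.21 and the oxidative phosphorylation one -0.09. As macrophage, matrix and heat shock lists stood higher in the same hearts (medians 0.26, 0.58 and 0.27), a change in the mix of cells or in handling was not separated from these lower values. Leaving out any single array ended the calls of Kcnip2 and Pfkm.

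Extracellular matrix and fibrosis genes stood higher as a list, with 29 of 31 members positive and a median of 0.58 (camera adjusted p = 1.02e-11; adjusted p = 0.436 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose by 1.72 (SE 0.29, adjusted p = 0.0415) and the type III collagen gene Col3a1 by 0.55 (SE 0.10, adjusted p = 0.0481). These were the 2 members past the threshold, against 6 when adjusted over the list alone. Col1a1 (0.40, adjusted p = 0.128) and Thbs1 (0.67) did not pass. The list median ranged from 0.26 without wild type replicate 3 to 0.92 without wild type replicate 1, and leaving out any single array ended the call of Col3a1. Timp1 kept its call only without knockout replicate 3. Markers of fibroblasts, the main matrix-producing cells, did not pass as a list (median 0.25, adjusted p = 0.0571), with 0 of 14 members past the limma threshold and 4 at an unadjusted p under 0.05. That list passed in 5 of 17 alternatives, among them without wild type replicate 1 (0.28, adjusted p = 0.00535) and without wild type replicate 2 (0.39, adjusted p = 0.00691), and its median was 0.02 without wild type replicate 3.

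The list of cytokine and adhesion genes that are targets of the transcription factor NF-kB stood higher in knockout hearts, with 18 members positive and 4 negative. Of 22 members, 7 rose over all probe sets and 9 when adjusted over the list alone, with 0 falls in either. Besides Il6, these were the chemokine genes Ccl3 (1.43, SE 0.11, adjusted p = 0.000980), Ccl4 (1.13, SE 0.10, adjusted p = 0.00124) and Ccl2 (0.81, outside the naming rule), the prostaglandin synthase gene Ptgs2 (1.76, SE 0.15, adjusted p = 0.00124), Tnf (1.10, SE 0.12, adjusted p = 0.00485) and Il1b (1.09, SE 0.10, adjusted p = 0.00250). Il6 went from 2.35 ± 0.41 to 5.03 ± 0.59 and Tnf from 4.10 ± 0.11 to 5.20 ± 0.18 (SD, n = 3). A second, dimmer probe set of Ptgs2 was at 0.23 and did not pass. Nor did the adhesion genes Icam1, Vcam1 and Sele at their main probe sets. The list median was 0.38 (camera adjusted p = 2.07e-14; adjusted p = 0.0744 with an estimated correlation), and 6 or 7 members passed with any single array left out. In the same hearts the heat shock list had a median of 0.27 and the macrophage and monocyte markers one of 0.26. The list of TLR4 pathway components runs from the receptor and its adaptors to kinases, NF-kB subunits and the inhibitor Nfkbia. It did not pass (median 0.08, camera adjusted p = 0.216). Of its 16 members 0 passed by limma at their main probe set and 3 had an unadjusted p under 0.05, with Tlr4 at -0.10 (SE 0.16, adjusted p = 0.899), Cd14 at 0.38 and the NF-kB inhibitor Nfkbia at 0.59. Of the 5 probe sets of Nfkbia, 1 other than the main one passed (0.72, adjusted p = 0.0239). Interferon-stimulated genes did not pass either, with a median of -0.04 (adjusted p = 0.472) and 0 of 18 members past the limma threshold (1 at an unadjusted p under 0.05). Leaving out single arrays turned the direction of the list, which passed as lower without wild type replicate 3 (-0.27, adjusted p = 0.000845) and as higher without wild type replicate 2 (0.10, adjusted p = 0.00396).

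Immediate early genes, which are switched on within minutes by growth factors, stretch and stress, were positive in 17 of 17 cases. Of these, 4 rose over all probe sets and 14 when adjusted over the list alone. They were Egr2 (2.19, SE 0.37, adjusted p = 0.0444), Atf3 (1.66, SE 0.17, adjusted p = 0.00485), Ier3 (1.23, SE 0.10, adjusted p = 0.00124) and Btg2 (1.10, SE 0.15, adjusted p = 0.0179). A probe set of Egr3 other than its main one also passed (1.04, adjusted p = 0.0347). The list median was 0.71 (camera adjusted p = 9.38e-17; adjusted p = 0.306 with an estimated correlation). With single arrays left out, Egr2 kept its call only without wild type replicate 3, and 2 to 4 members passed. Heat shock genes, listed beforehand as a sign of tissue handling and stress, stood higher in the same hearts, with a median of 0.27 (camera adjusted p = 4.40e-05 among the technical lists; adjusted p = 0.0480 with an estimated correlation), which was 0.15 without wild type replicate 3. Of 11 heat shock members 2 rose, Hspa1a and Hspa1b, whose transcripts are nearly identical and can share probes. Hspb1 at 0.39 and Dnaja1 at 0.37 did not pass.

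**Figure D3:**
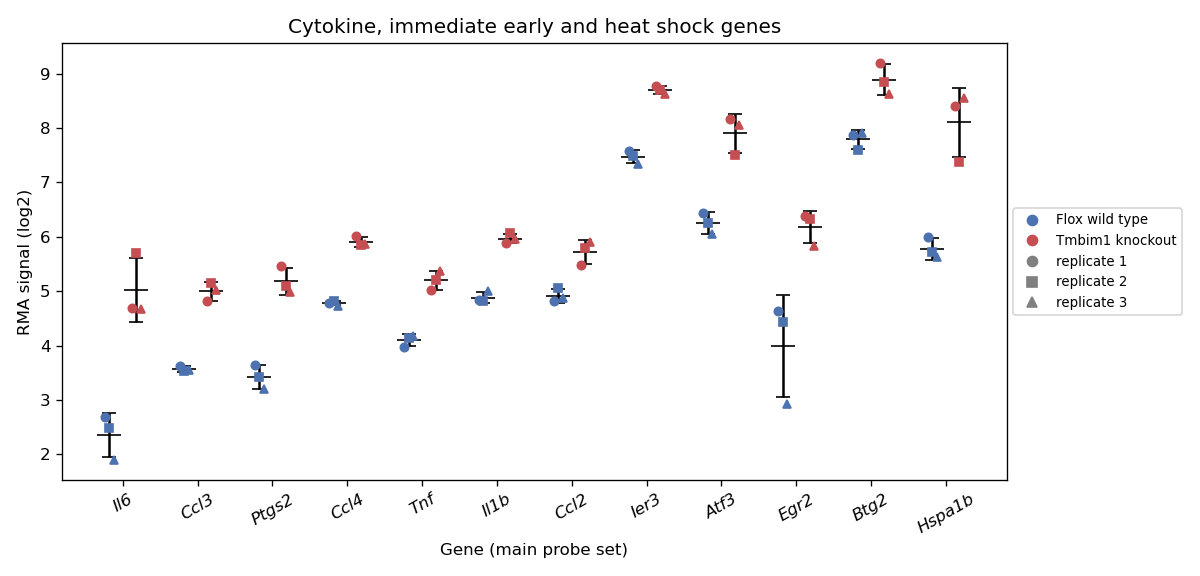
Signal (log2) of 7 NF-kB target genes, 4 immediate early genes and Hspa1b in each array, with 1 symbol per mouse and the mean and SD of 3 mice as a bar. For each of the 12 genes the 3 knockout hearts lay above the 3 wild type hearts, by 0.81 on average for Ccl2 and 2.68 for Il6. All 12 had passed the threshold as higher, and all 161 probe sets past it had the groups apart, so the separation is no further finding.

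Among cell types, macrophage and monocyte markers stood higher as a list (median 0.26, camera adjusted p = 2.72e-05; adjusted p = 0.436 with an estimated correlation), with 0 of 21 members past the limma threshold at their main probe set, 8 at an unadjusted p under 0.05 and 3 when adjusted over the list alone. Lyve1, a marker of resident macrophages, was at 0.79, Lgals3 at 1.92 and the complement gene C1qa at 0.42. The median was 0.12 without wild type replicate 3 and 0.44 without wild type replicate 2. Neutrophil markers did not pass (median 0.08, adjusted p = 0.0525), with the alarmin genes S100a9 at 1.32 and S100a8 at 0.95, both counted as higher when adjusted over the list alone. The neutrophil list passed in 8 of 17 alternatives, including without wild type replicate 3 (adjusted p = 0.0161), knockout replicate 1 (0.0314) and knockout replicate 2 (0.0316), and its median was 0.02 without wild type replicate 2. Cell cycle genes had a median of 0.23, with 0 of 22 members past the limma threshold and 2 at an unadjusted p under 0.05 (camera adjusted p = 0.00117; adjusted p = 0.571 with an estimated correlation), and the list lost its call without wild type replicate 3 (median 0.12, adjusted p = 0.144).

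The other 13 lists did not pass, and 0 of their 168 members did by limma at their main probe set, with 27 at an unadjusted p under 0.05. They were T and NK cell markers (median -0.10), B cell markers (-0.09), endothelial markers (0.08), smooth muscle and pericyte markers (0.04), red blood cell markers (0.10), adipocyte markers (-0.05), skeletal muscle markers (-0.06), and Schwann cell and neuronal markers (-0.01). Nor did unfolded protein response genes (-0.06), apoptosis genes (0.05), lysosome genes (0.00061), the ESCRT and multivesicular body genes that sort membrane proteins for degradation (0.03) or oxidative stress genes (0.20). Oxidative stress genes passed without wild type replicate 2 (0.25, adjusted p = 0.0496) or knockout replicate 2 (0.23, adjusted p = 0.0165), and smooth muscle and pericyte markers without knockout replicate 2 (0.15, adjusted p = 0.0401). The TMBIM family list, with Tmbim1 among its 7 members, had a median of -0.12 (adjusted p = 0.0841) and passed by camera with the dim probe sets left out and with the mean of all probe sets per gene (adjusted p = 0.0224). T and NK cell markers passed only without both knockout replicate 1 and wild type replicate 3 (-0.04, adjusted p = 0.0490). Clock genes, sex-linked genes and chromosome 1 neighbours of Tmbim1, the remaining technical lists, did not pass (medians 0.01, -0.04 and -0.04). All 6 arrays had Xist near the floor and the Y-linked Eif2s3y between 7.95 and 8.29. In total 10 of 29 lists passed by camera, 7 higher and 3 lower, while 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) and 5 passed by fry, which asks only whether a list's own genes move on balance. Of those 5, the fetal, NF-kB target and immediate early lists were among the 10, while the TMBIM family and the neutrophil markers were not. Splits of the 6 arrays that mix the genotypes gave 3 to 14 lists by camera. A camera call with the preset correlation is therefore weak ground for a genotype difference, however small its adjusted p.

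**Figure D4:**
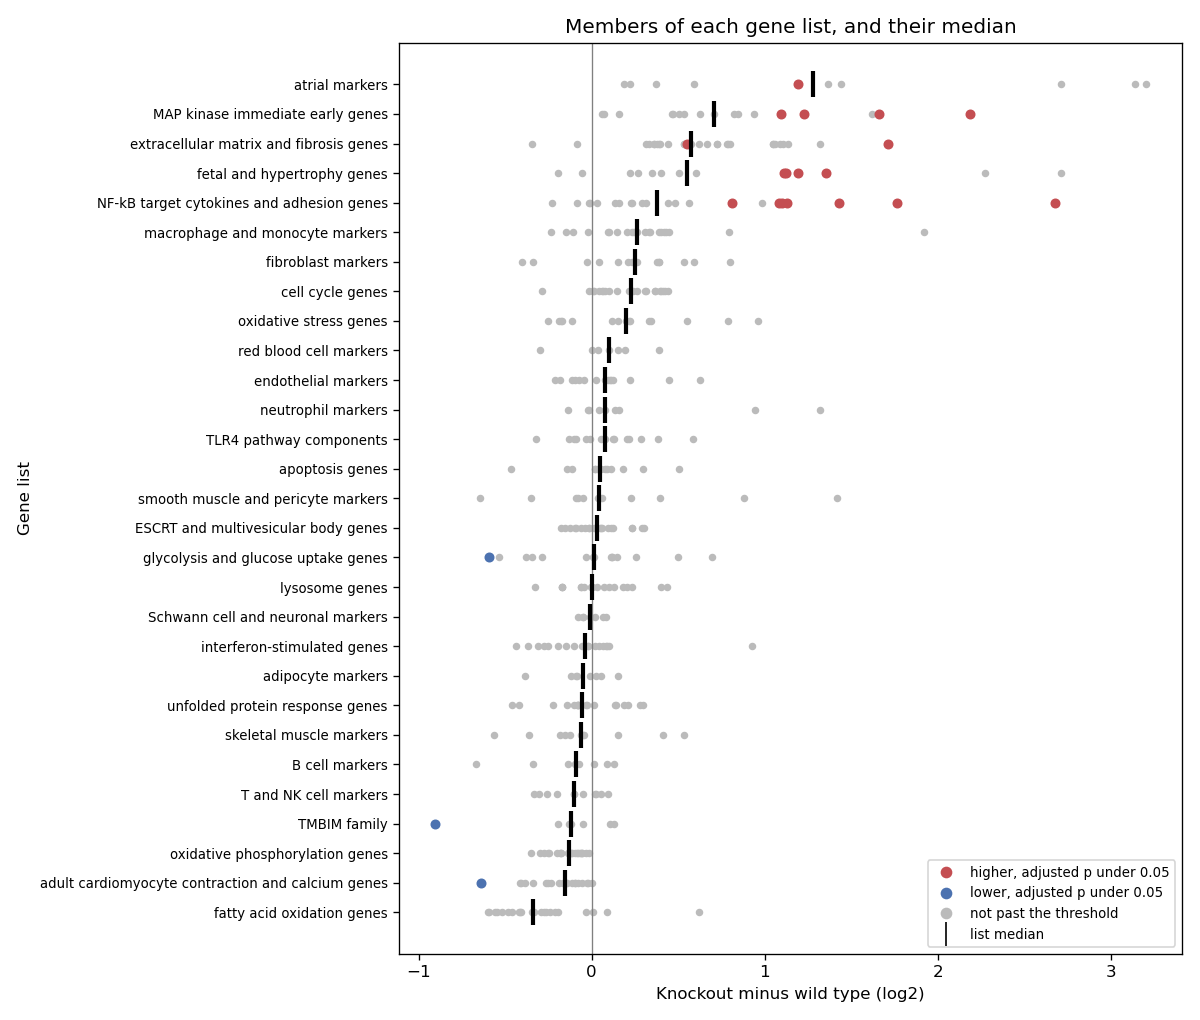
Knockout minus wild type (log2) of each measured member of the 29 biology and cell type lists, with 1 dot per gene and a vertical tick at the list median. Coloured dots passed the limma threshold, and the atrial, immediate early, matrix and fetal lists have the highest medians, from 1.28 to 0.55.

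Control probe sets for both ends of 2 transcripts gave a check of RNA integrity. The 3-prime minus 5-prime difference of Actb was 0.43 ± 0.11 in wild type and 0.31 ± 0.01 in knockout arrays (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 can give). For Gapdh the exact permutation p was 0.5.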

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

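The alternatives were planned, except that the fit without knockout replicate 1 and wild type replicate 3 was chosen after seeing the data. The count of 161 probe sets lay between 141 and 174 with limma-trend, a robust prior, array weights, a second quantile normalization, median centring and the filter on dim probe sets, and the share of higher calls stayed near the main 56.5% under both scalings (57.5% and 57.4%). Testing 1 probe set per gene gave 102 calls, 41 of them lower, from fewer tests. Leaving out both arrays gave 29, with 26 higher and 3 lower, from fewer samples. The ordinary two-sample test gave 1, with 0 higher and 1 lower. An unadjusted p under 0.05 with a fold change of 1.5 gave 547, with 322 higher and 225 lower. With each array left out in turn, the total ranged from 38 to 86, the higher calls from 32 to 58 and the lower calls from 6 to 28, and higher calls made up to 84.2%. Fewer arrays mean fewer calls by construction, and why lower calls were lost more often was not tested.

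Tmbim1 ranged from -0.96 to -0.83 with each array left out, lost its call without knockout replicate 2, and was at -0.96 without both arrays (adjusted p = 0.0607), with fewer samples. Across 29 lists, 10 passed in the main test, 0 with an estimated correlation and 5 by fry (2 of them outside the 10), and 10 to 13 with each array left out. The camera run with an estimated correlation differed from the main test only in that setting, so the drop from 10 to 0 follows from it. In camera, however, the setting also lowers the degrees of freedom of the test, from about the number of genes to the residual ones of the arrays. How much of the drop came from correlation between genes was therefore not separated. Why fry differed was not tested. The interferon list median, -0.04, reversed to 0.10 without wild type replicate 2 (adjusted p = 0.00396) and passed as lower, at -0.27, without wild type replicate 3 (adjusted p = 0.000845); the cause was not tested. Of 36 named genes past the threshold besides Tmbim1, 11 kept their call in all 15 alternatives and 0 reversed. Those 15 do not include the ordinary two-sample test, in which 0 probe sets passed as higher. The 11 genes all rose, so none of them passed in that test.

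With the replicate number as a block, 168 probe sets passed (107 higher, 61 lower), 109 of them shared with the main 161, and 7 of the 36 named genes lost their call. Whether equal numbers pair the mice is not known. Deviations of same-numbered arrays correlated at 0.06, 0.14 and 0.02, and those of other pairs between -0.14 and 0.08. Wild type replicates 1 and 2 correlated best with the knockout of the same number, and wild type replicate 3 with knockout replicate 1. These values do not settle the question. The robust prior was not run for lists, which camera does not offer, and Tmbim1 had no other probe set. Signal over background could not be judged without detection calls, so changes of dim genes such as Il6 may be understated; with the dim probe sets left out, 152 probe sets passed.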

Other observations

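Genes in the next 2 paragraphs were chosen after their values were seen. Further signalling genes outside the lists rose in knockout hearts. They included the cytokine subunits Il12a (1.61, limma adjusted p = 0.000362) and Il12b (1.30, adjusted p = 0.00671), the type I interferon gene Ifnb1 (1.56, adjusted p = 0.00101), the cytokine feedback inhibitor Socs3 (1.20) and the acute phase transcription factor Cebpd (1.58). Ifnb1 went from 3.51 ± 0.23 to 5.07 ± 0.05 and Il12a from 2.05 ± 0.11 to 3.66 ± 0.13 (SD, n = 3), levels at the dim end of the arrays, and a second probe set of Il12b was at -0.01. The epidermal growth factor receptor ligands Hbegf (1.21) and Ereg (1.30) and the receptor inhibitor Errfi1 (1.12) rose too. Among proteases, Adamts1 (1.26), the collagen-degrading Ctsk (1.33) and Mmp3 (0.93) were higher and Htra1 (-1.05) was lower.

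The stretch-responsive Ankrd2 (0.89) and the actin-binding Abra (1.39) rose, while Asb14 (-0.69), Klhl30 (-0.73) and the thin filament protein gene Lmod3 (-0.74) fell. The glycolytic regulator Pfkfb2 fell by 0.77. Ppargc1a, a coactivator of mitochondrial genes, fell in 2 of 5 probe sets (-0.98 and -0.82), and its main probe set was at -0.56 and did not pass. All 5 of its probe sets were negative. The mineralocorticoid receptor gene Nr3c2 (-0.60) and the endothelin receptor gene Ednrb (0.88) also passed.

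Of the tests below, those of cross-hybridisation, an exchange of arrays, macrophages, handling and RNA degradation were chosen only after the result was seen. The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 161 probe sets, and the highest other gave 0, so 1 of 10 splits gave as many. For lists by camera the real split gave 10 and the highest other gave 14, so 4 of 10 splits gave as many. The splits that mix the genotypes gave 3 to 14 lists, so the number of lists passing camera does not mark the genotype.

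Wdfy1 had the smallest p of the probe sets tested, with 4 of its 5 probe sets past the threshold as higher, which argues against cross-hybridisation of a single probe set. Wdfy1 lies on chromosome 1 like Tmbim1, 56 measured genes away, so strain variants carried along with the altered Tmbim1 allele may be a candidate explanation. Among 199 measured neighbours of Tmbim1, 1 passed (Kcne4 at 0.68, 53 measured genes from Tmbim1), against 96 of 17673 other genes (two-sided Fisher's exact p = 1), which leaves this open because variants need not alter many genes. Over the whole of chromosome 1, counted after seeing the data and without Tmbim1 and Wdfy1, 13 of 1043 genes passed (Fisher's exact p = 0.00412, 0.0824 when adjusted over 20 chromosomes). Apart from Kcne4, the nearest of them was Usp40, 117 measured genes from Tmbim1, and the farthest was Atf3, at 696. Several, such as Ptgs2, Btg2, Atf3 and Col3a1, belong to lists that stood higher. The count is therefore no test of a segment close to Tmbim1. Whether the Flox mice were littermates of the knockouts is not known here. A difference in strain background elsewhere in the genome therefore stays open too, and a count of neighbours cannot show it. An effect of Tmbim1 loss on Wdfy1 also stays open and was not tested.

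In knockout replicate 1, 8 genes lay more than 3 above the mean of the other arrays, against 0 in any other array, and beside Myl4, Myl7, Sln, Fgf12 and Dkk3 they were Mybphl (5.04), Mlana (4.63) and Tmem163 (3.04). An exchange with a wild type array is argued against by its Tmbim1 signal, 0.80 below the lowest wild type array. Atrial tissue left on that heart sample is a candidate explanation: a second atrial list of 12 genes, written before its values were seen, had 8 measured members with a median of 0.30 in that array, at the 100th percentile of 10000 matched random lists, whose own median was -0.00084. Kcnj3 (1.48), Hamp (1.58) and Pam (0.93) led it, and Pam is abundant in every array. No biological explanation was tested, since the genotype is shared with 2 hearts that lack the pattern.

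The 7 NF-kB targets that passed rose by 0.81 or more, with a median of 1.13. Whether more macrophages of unchanged activity are the whole cause stays open. The mean of all 22 targets was 0.62 higher in knockout hearts against 0.31 for the mean of the macrophage markers. The gap of 0.30 exceeded its SD (0.13 in wild type and 0.10 in knockout arrays). That target mean was carried largely by the 7 that passed, and the list medians lay closer, at 0.38 and 0.26. Targets less markers was -2.38 in the highest wild type array and -2.31 in the lowest knockout array. The comparison of means was also the 3rd form of the test. The 1st rested only on targets that passed and decides nothing. The 2nd left the question open, with a span of the markers between single arrays (0.61) above the median of all targets (0.38). Slower handling of the knockout hearts before preservation may contribute, since the heat shock list (median 0.27) and the immediate early list passed by camera as higher in the same arrays, the latter not with an estimated correlation (adjusted p = 0.306). RNA degradation in the knockout arrays would raise the end difference of the control transcripts there, but that difference was lower (-0.10 in knockout minus wild type). The controls thus gave no sign of it, yet the value lay within the wild type SD of 0.12, so RNA degradation stays open. A few newly activated or infiltrating cells and an effect of Tmbim1 loss on signalling within heart cells also stay open and were not tested.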
